A study of Mus musculus with 48 samples.

How the data were processed

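RNA was extracted from both ventricles of 48 male mice, 6 in each of 8 groups, and 1.3 ug of total RNA per animal went into libraries with the SMARTER mRNA-seq kit after an RNeasy Mini Plus extraction, per the labels. The deposited table holds raw counts of reads per gene, 1 column per library, which the authors made with bcl2fastq 2.18.0.12, STAR 2.7.9a and HTSeq 0.11.1 on genome build GRCm39, according to the submitters' processing notes. These notes give the tools without their role or order. The annotation release, the strandedness, the read filters and the time of day of tissue collection are not given in the sources used here. Genes that overlap another gene on the opposite strand are therefore uncertain, as are genes that share reads with near-identical copies, such as Ighg2c, Ces1d and Scd4.

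The table listed 53700 genes by Ensembl identifier. Of these, 52093 (97.0%) were matched by identifier to a symbol of the GENCODE M21 annotation of build GRCm38, used for names and neighbour order only, and they held 95.13% of the assigned counts. Positions on GRCm39 are not reported because no annotation of that build was at hand. The 5 summary lines of HTSeq (no feature, ambiguous and the like) were left out of the totals. All columns matched a labelled library, no pair of libraries was identical, and 34803 genes had a count in at least 1 library. Assigned counts per library are given at the start of the results. At the lowest depth 1 CPM is about 13 reads before TMM scaling, so genes near 1 CPM are measured with counting error as well as spread between animals.

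Genes were kept by filterByExpr over the 8 groups, which left 16623. Counts were normalised with TMM and fitted with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, as a single model of 8 group means with 40 residual degrees of freedom. Each of the 4 lines was compared with its littermate controls, and these comparisons share no libraries. A further 5 contrasts tested differences between effects: each knockout against Cre alone, CBK/CEK against CBK, and the departure of CBK/CEK from the sum of the single knockouts with Cre counted once. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, and genes were called at an adjusted p under 0.05. These p-values measure the spread between these animals, since the labels call each library a biological replicate.

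The choices of tests, gene lists, named genes and other settings were made before the data were examined. The 31 lists hold 685 memberships, 664 of them of measured genes, with some genes in more than 1 list, and cover the clock and its E-box and RORE outputs, hypertrophy and sarcomere, extracellular matrix, metabolism, ion channels, insulin signalling, stress responses, inflammation, growth, and markers of cell types. Each list was tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. Fry (limma) asked instead whether a list changed at all, not whether it differed from other genes, so its p-values answer another question. All were adjusted over the 31 lists. The lists that hold Nfil3 were also tested without it, a choice made after the data were seen. Named genes were the targets, Myh6 and the clock genes, per line the 10 highest and 10 lowest called genes with a symbol and at least 1 CPM in a group, up to 4 called members per list, and up to 6 called genes per direction for differences. Of the genes that met this rule, 2 are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

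Results were also computed, as fixed in advance, with RLE normalisation, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 6 libraries, a fit of each line's 12 libraries alone, the replicate number as a block, a covariate for cohorts of animal numbers, and an adjusted p of 0.01 for shared genes. After the data were seen, fits without Cre CON replicate 1, without WT replicate 1, without 5 libraries of outlying composition (CBK replicates 3 and 5, CEK replicates 4 and 5, BMAL1/E4BP4 FLOX replicate 6), and with the level of ENSMUSG00000119584 as a covariate were added. For each contrast 100 splits of the 12 libraries of every line into 6 and 6, the real one included, were also fitted.

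The steps were tested on simulated data with 200 of 16623 genes changed per line. With a common spread, 76.1% to 89.6% of genes changed by 2-fold were recovered, 47.8% to 58.2% of those changed by 1.5-fold, and 2.5% to 5.7% of calls were false. With the spread of each line taken from its own libraries, 21.0% of CBK calls, 13.2% of CEK calls, 11.5% of CBK/CEK calls and 0 Cre CON calls (of 142) were false, against 2.9% to 4.3% when lines were fitted alone. The median biological coefficient of variation was 23.1% in the CBK line, 21.0% in the CEK line, 20.5% in the CBK/CEK line and 14.3% in the Cre line. The pooled spread is therefore too small for the CBK line and too large for the Cre line. In the list test, 1 of 200 random lists had a p under 0.05.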

Results

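RNA of both ventricles of the heart was sequenced from 48 male C57BL/6 mice of 4 lines. Each line held 6 animals with a floxed gene, Cre recombinase or both, and 6 littermates as controls. CBK mice lack the clock gene Bmal1 in heart muscle cells, CEK mice lack E4bp4 there, and CBK/CEK mice lack both. Their controls, BMAL1 FLOX, E4BP4 FLOX and BMAL1/E4BP4 FLOX, carry the floxed genes without Cre. Cre CON mice carry Cre, driven by the Myh6 promoter, without a floxed gene, and their littermates are WT. Bmal1 carries the symbol Arntl and E4bp4 the symbol Nfil3 in the annotation used for names. Libraries held 13128833 to 28407868 counts assigned to genes, except WT replicate 1 with 126338949. Mitochondrial transcripts took 17.6% ± 4.56 (SD, n = 6) of the assigned counts in CBK and 21.4% ± 2.94 in BMAL1 FLOX. ENSMUSG00000119584, unnamed in the annotation used, took 17.9% ± 10.2 in CEK and 10.3% ± 4.18 in E4BP4 FLOX, against 0.738% ± 0.241 in WT and 0.883% ± 0.137 in Cre CON. The share of records assigned to genes was also lower in both groups of the CEK line. It was 61.8% ± 4.20 in CEK and 63.1% ± 0.938 in E4BP4 FLOX, against 69.3% ± 1.29 in WT and 69.9% ± 0.563 in Cre CON. Levels below are counts scaled to the TMM-normalised library size (CPM), each the mean ± SD of 6 libraries. Changes are log2 fold changes with their standard error (SE), called at an edgeR adjusted p under 0.05 over 16623 genes.

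The RNA levels of the targeted genes themselves were compared in all 8 groups, with whole-gene counts. Nfil3 fell from 8.07 ± 1.40 CPM in E4BP4 FLOX to 0.644 ± 0.095 CPM in libraries labelled CEK, a log2 fold change of -3.60 (SE 0.20, n = 6 per group, edgeR adjusted p = 1.84e-19). It fell from 9.34 ± 1.65 to 1.84 ± 0.649 CPM in libraries labelled CBK/CEK, a log2 fold change of -2.35 (SE 0.17, edgeR adjusted p = 1.26e-15). In libraries labelled CBK it rose instead, from 10.9 ± 2.03 to 38.9 ± 5.2 CPM, a log2 fold change of 1.83 (SE 0.15, edgeR adjusted p = 6.48e-14). Arntl counts were higher, not lower, in libraries labelled CBK, at 8.41 ± 2.41 CPM against 1.04 ± 0.381 CPM, a log2 fold change of 3.00 (SE 0.33, edgeR adjusted p = 1.41e-09). They were also higher in CBK/CEK, at 11.8 ± 0.894 CPM against 0.987 ± 0.327 CPM (edgeR adjusted p = 4.27e-11). Whole-gene counts pool all exons, and the sources used here do not say which part of Arntl Cre removes. These counts therefore do not measure whether the floxed part was lost, and the cause of the rise was not tested. In WT, Cre CON and CEK, Arntl stood at 1.01 ± 0.309, 1.60 ± 0.80 and 0.682 ± 0.553 CPM, and it was not called in Cre CON or CEK. Nfil3 stood at 9.89 ± 1.41 CPM in WT and 9.56 ± 1.72 CPM in Cre CON. Myh6 was not called in any line, with log2 fold changes of -0.11 in CBK, -0.12 in CEK, -0.03 in CBK/CEK and -0.06 in Cre CON.

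**Figure D1:**
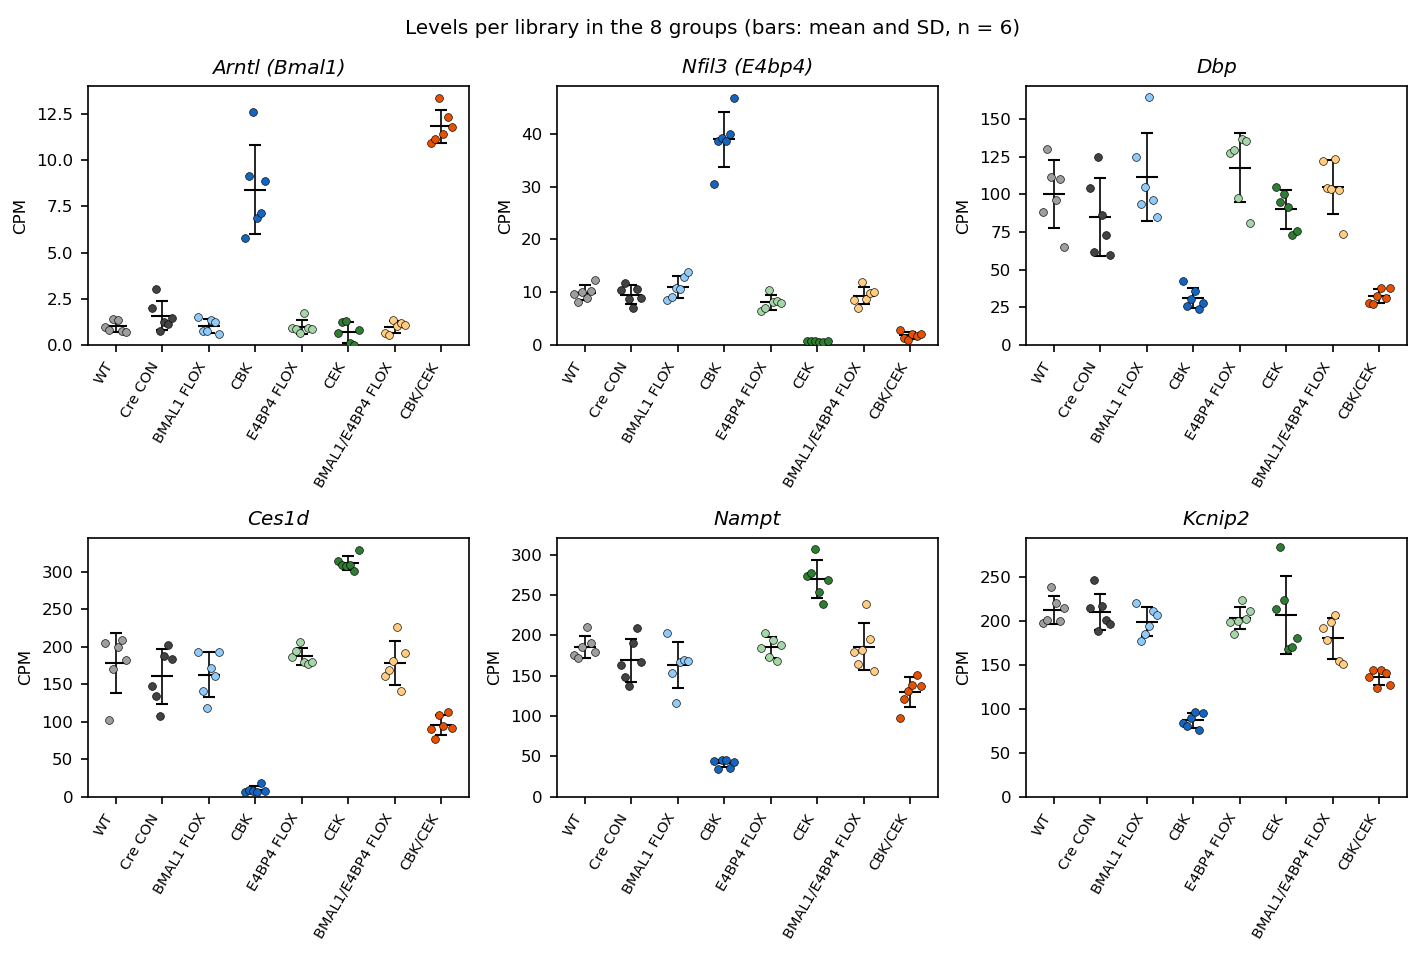
Normalised CPM (linear axes) of Arntl, Nfil3, Dbp, Ces1d, Nampt and Kcnip2 in the 8 groups; points are libraries, bars the mean and SD of 6. Nampt fell to 41.0 CPM in CBK and 129 CPM in CBK/CEK, against 163 and 186 CPM in their controls.

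Cre CON was compared with WT to measure what the Cre transgene does on its own. The transcript of Ndnf, which encodes a secreted neurotrophic protein, rose from 6.78 ± 1.85 to 17.6 ± 5.33 CPM, a log2 fold change of 1.38 (SE 0.21, n = 6 per group, edgeR adjusted p = 0.00049). Dcakd fell by 0.49 (SE 0.10, edgeR adjusted p = 0.0381) and the phosphatase subunit gene Ppp2r3a by 0.56 (SE 0.11, edgeR adjusted p = 0.0222) on the log2 scale, Dcakd from 44.4 ± 1.86 to 31.7 ± 6.56 CPM. These 3 were the genes called by edgeR, and DESeq2 called 19 genes. At an unadjusted p under 0.05 were 606 genes, fewer than the 831 expected by chance. The pooled spread is too large for this line, with a median biological coefficient of variation of 14.3% against 20.5% to 23.1% in the others. The low counts therefore do not show that Cre changed little. Cre CON replicate 1 stood at 7.48 CPM for Ndnf and 43.8 CPM for Dcakd, within the range of WT, and at 206 CPM for Ppp2r3a, where the lowest WT library had 209 CPM. Without it 16 genes were called, among them Ndnf at 1.53, the dystrophin gene Dmd at -0.92 and Pfkfb1 at -1.02. Leaving out the Cre CON library nearest to WT raises the count and the changes in part by construction. Dmd and Pfkfb1 were chosen after their values were seen. In a fit of these 12 libraries alone, 12 genes passed, none of them among the 3.

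No member of the 31 gene lists fixed in advance was called by edgeR in Cre CON over all genes. Of their 664 measured memberships, 80 had an unadjusted p under 0.05 and 5 passed with DESeq2. Camera placed 14 lists past the threshold, 7 of them also with an estimated correlation, and 2 passed with fry, macrophage markers and branched-chain amino acid and ketone catabolism (fry adjusted p = 0.00725 for each). Extracellular matrix genes (8 of 38 higher adjusted over the list alone, median log2 fold change 0.33, camera adjusted p = 3.83e-20), inflammatory cytokines (0 of 24, 1.68e-05), macrophage markers (5 of 18 higher, 1.95e-15) and fibroblast markers (0 of 13, 0.000664) shifted up. Fatty acid oxidation (0 of 38 adjusted over the list alone, camera adjusted p = 1.31e-11), branched-chain amino acid and ketone catabolism (6 of 25 lower, 2.15e-14) and endothelial markers (0 of 15, 0.00554) shifted down. With fry, adjusted p was 0.0779 for extracellular matrix, fatty acid oxidation and endothelial markers, 0.0536 for cytokines and 0.099 for fibroblast markers, where fry tests a list against no change and camera against the other genes. The calls lost with an estimated correlation were the E-box outputs (adjusted p = 0.289 with an estimated correlation), sarcomere genes (adjusted p = 0.246 with an estimated correlation), glucose metabolism (adjusted p = 0.289 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.311 with an estimated correlation). Also lost were the p53 response (adjusted p = 0.0883 with an estimated correlation), immediate early genes (adjusted p = 0.578 with an estimated correlation) and erythroid markers (adjusted p = 0.416 with an estimated correlation). Without Cre CON replicate 1, camera adjusted p was 0.0521 for sarcomere genes and 0.221 for immediate early genes; without WT replicate 1 it was 0.271 for immediate early genes and 0.0697 for erythroid markers. Over 6 alternatives these adjusted p ranged from 0.00278 to 0.287, from 0.034 to 0.686 and from 0.0227 to 0.454. Median and mean differed in sign for the RORE, triglyceride, ion channel, insulin, atrial and adipocyte lists, none of which passed.

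CBK was compared with BMAL1 FLOX for the effect of losing Bmal1 in heart muscle cells. BMAL1 FLOX carries no Cre, so the comparison also holds the effect of Cre. Transcripts of the clock outputs Dbp and Nr1d2 fell, Dbp from 111 ± 29.4 to 31.0 ± 6.79 CPM (log2 fold change -1.84, SE 0.18, n = 6 per group, edgeR adjusted p = 7.57e-11) and Nr1d2 from 89.2 ± 11 to 27.5 ± 5.34 CPM (edgeR adjusted p = 7.21e-18). Npas2, which encodes a partner of BMAL1, rose by 2.31 (SE 0.24, edgeR adjusted p = 1.16e-10), from 1.66 to 8.24 CPM. Nampt, whose product makes a precursor of NAD, fell from 163 ± 28.3 to 41.0 ± 4.92 CPM (log2 fold change -1.99, SE 0.11, edgeR adjusted p = 6.5e-20). The cell-cycle inhibitor gene Cdkn1a rose from 11.3 ± 4.64 to 158 ± 53.2 CPM (log2 fold change 3.81, SE 0.25, edgeR adjusted p = 1.5e-15).

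In all, 1396 genes were called in CBK, 673 higher and 723 lower, of which 146 rose and 179 fell by more than 2-fold. A fit of these 12 libraries alone called 857, 440 higher and 417 lower, and in simulated data 21.0% of the calls of the pooled fit were false for this line. Higher genes outnumbered lower ones also with RLE (751 and 660), DESeq2 (880 and 755) and a filter of 1 CPM (812 and 673), so the balance of directions is not settled. Among the highest were Sprr1a at 6.39, Iyd at 4.41, Cbln1 at 3.15, Mrln at 2.96 and the transporter gene Slc41a3 at 2.93, which rose from 36.7 ± 5.65 to 279.6 ± 36.4 CPM. The carboxylesterase gene Ces1d fell from 163 ± 29.6 to 8.95 ± 4.57 CPM, a log2 fold change of -4.19 (SE 0.20, edgeR adjusted p = 6.33e-21). Pde11a changed by -3.77, Ano4 by -2.58 and the ketone enzyme gene Bdh1 by -2.44. The antibody gene Ighg2c stood at 0.292 ± 0.168 CPM in CBK and 5.25 ± 1.05 CPM in BMAL1 FLOX, while WT, Cre CON and CEK stood at 6.34 ± 2.28, 4.73 ± 1.31 and 5.35 ± 1.51 CPM. HTSeq tallied reads that align to more than 1 place on a summary line, so counts of Ces1d and Ighg2c may miss reads shared with near-identical gene copies. Of the 93 named genes called in CBK, 70 had no overlap between the 6 CBK and the 6 control libraries, which follows in part from their choice as called genes.

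Of 24 clock genes, 7 were called higher and 11 lower in CBK (8 and 11 adjusted over the list alone). Their median log2 fold change was -0.26, their mean 0.02, and camera pointed down at an adjusted p of 0.0296, which became adjusted p = 0.41 with an estimated correlation. Clock rose by 0.95 and Cry1 by 1.01, while Ciart changed by -2.0, Per3 by -1.07, Tef by -0.97, Nr1d1 by -0.90 and Per1 by -0.73. Per2 was not called, at -0.35. Of 15 targets of E-box elements, through which BMAL1 acts, 12 fell, with Wee1 at -1.51, and 1 rose (12 and 1 also adjusted over the list alone, camera adjusted p = 3.36e-29). All 5 genes with elements for the REV-ERB and ROR receptors rose (5 adjusted over the list alone, camera adjusted p = 7.22e-26). This list and the clock list hold Arntl, the gene targeted in CBK, at 3.00, and were not tested without it.

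**Figure D2:**
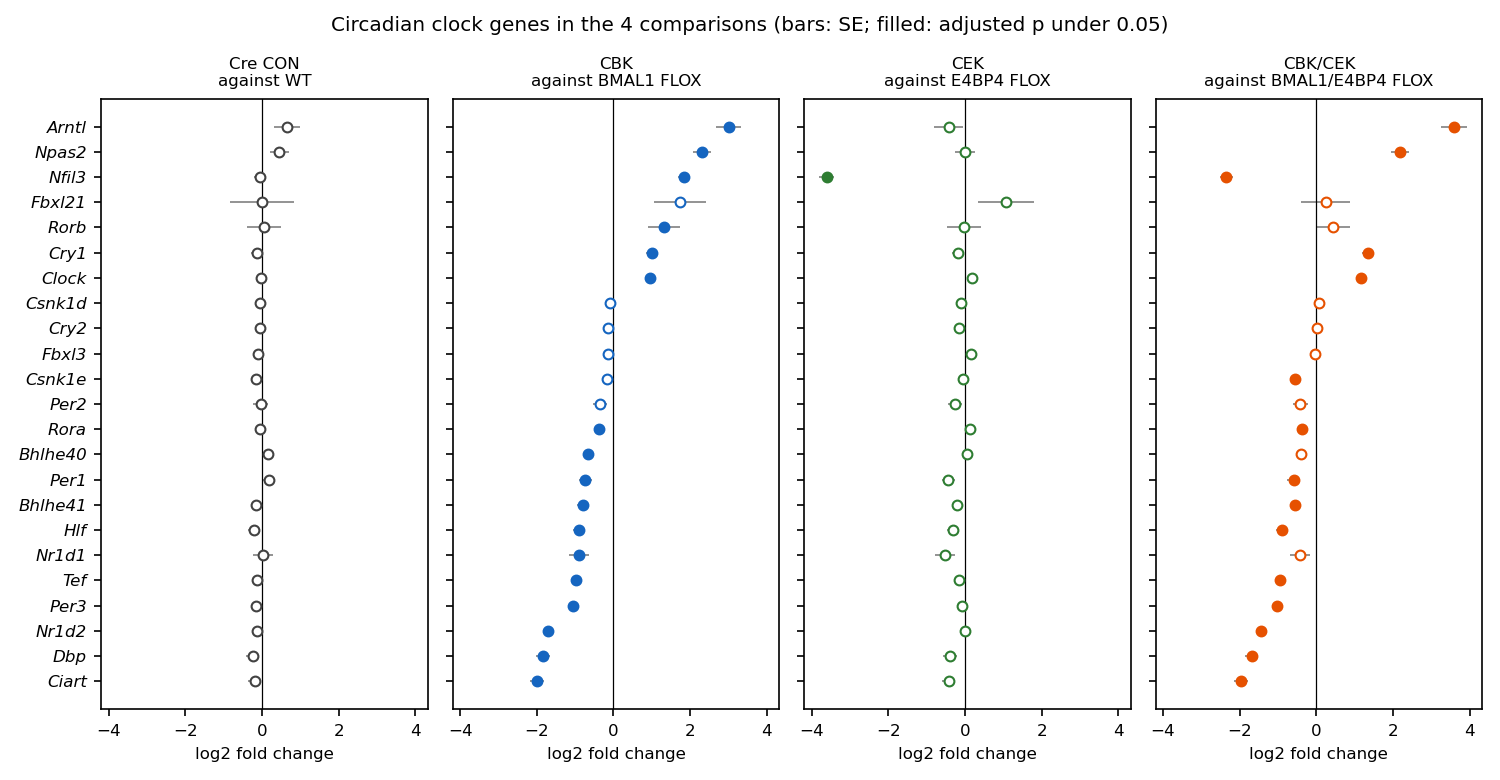
Log2 fold change (bars, SE) of 23 of the 24 clock genes in the 4 comparisons of 6 against 6 libraries; filled points have an edgeR adjusted p under 0.05. Arntl, Npas2, Clock and Cry1 rose in CBK and in CBK/CEK, where Arntl changed by 3.00 and 3.59.

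Heart stress genes rose in CBK. Of 20 hypertrophy and fetal genes, 9 were called higher and 1 lower (11 and 2 adjusted over the list alone, camera adjusted p = 6.54e-08). The natriuretic peptide gene Nppb rose from 85.8 ± 44.7 to 225 ± 63.1 CPM (log2 fold change 1.39, SE 0.27, edgeR adjusted p = 0.000248). Nppb also stood higher in Cre CON than in WT, by 0.79 on the log2 scale, which was not called. Rcan1 rose by 1.72, Ankrd1 by 1.55 and the skeletal actin gene Acta1 by 1.38 (SE 0.42, edgeR adjusted p = 0.0289). Of 41 ion channel and calcium handling genes, 6 rose and 10 fell (8 and 12 adjusted over the list alone, camera adjusted p = 0.468). The pacemaker channel gene Hcn2 rose from 29.6 ± 5.17 to 102.5 ± 12.4 CPM and Hcn4 changed by -1.55. Kcnip2, which encodes a subunit of a cardiac potassium channel, fell from 199 ± 16.7 to 86.7 ± 8.16 CPM (log2 fold change -1.20, SE 0.09, edgeR adjusted p = 2.78e-14), and Kcne1 rose by 1.77. Among 20 sarcomere genes, 2 rose, with Mybpc3 at 0.63, and 1 fell (2 and 1 adjusted over the list alone). The gene that fell, Tcap, went from 2534 ± 531 to 663 ± 381 CPM.

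Metabolic genes moved both ways in CBK. Of 25 genes of branched-chain amino acid and ketone catabolism, 10 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 3.74e-07, adjusted p = 0.111 with an estimated correlation), with Bckdhb at -0.84, Dbt at -0.64 and Mccc2 at -0.49. Of 38 fatty acid oxidation genes, 5 fell (9 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.557 with an estimated correlation), with Ech1 at -0.63 and Hadh at -0.40. Of 26 genes of triglyceride and lipid synthesis, 4 rose and 4 fell (4 and 4 adjusted over the list alone), with Agpat3 at 0.61, Gpam at -0.75 and Dgat2 down from 371 ± 63.9 to 100.2 ± 13.8 CPM. Dgat2 at -0.74 and Slc41a3 at 0.62 also differed between BMAL1 FLOX and WT. Of 34 genes of glucose and glycogen metabolism, 6 rose and 6 fell (9 and 8 adjusted over the list alone), with Pfkfb1 at -1.77, Hk2 at -0.53 and Slc2a4 at -0.44. Of 39 oxidative phosphorylation genes, 1 was called, Sdhc at -0.33 (1 adjusted over the list alone).

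The stress response, insulin, antioxidant and autophagy lists had called members in both directions in CBK. Of 27 genes of the integrated stress and unfolded protein response, 5 rose and 2 fell (the same numbers adjusted over the list alone), with Gdf15 at 2.47, Mthfd2 at 1.78 and Herpud1 at -0.96. Of 28 insulin signalling genes, 1 rose, Ddit4 at 1.40, and 6 fell, among them Akt1 at -0.90 (1 and 6 adjusted over the list alone). Of 25 antioxidant genes, 2 rose, Nqo1 by 0.51, and 2 fell, and of 25 autophagy genes, 3 rose, Lamp1 by 0.28, and 2 fell, Pink1 at -0.41 (counts unchanged adjusted over the list alone). Cdkn1a and Phlda3, at 0.67, were the 2 of 19 p53 response genes called (2 adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.236 with an estimated correlation). Col8a1 at 0.64 and Tgfb2 at 0.38 were the 2 of 38 extracellular matrix genes called (2 adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.711 with an estimated correlation).

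Immune, growth and cell type lists held few called genes in CBK, and camera passed none of them. Ier3 changed by -1.25 among 23 immediate early genes, Cxcl12 by -0.48 among 24 cytokines, Gbp3 by -0.52 among 25 interferon genes and Cenpf by -0.74 among 26 cell cycle genes. Adjusted over the list alone, Ier3 and Cxcl12 passed. Cell type markers called were Pcolce at 0.57 and 1 more of 13 fibroblast genes, Kdr at -0.40 of 15 endothelial genes, Abcc9 at -0.77 of 12 mural genes, Ccr2 at 1.09 of 18 macrophage genes and Cidea at 0.92 of 11 adipocyte genes. Adjusted over the list alone, the counts were 2, 0, 2, 1 and 1. Kdr was not called without WT replicate 1 (edgeR adjusted p = 0.0509), which enters through the pooled spread, and its adjusted p ranged from 0.0278 to 0.384 over 11 alternatives. Lymphocyte, atrial, erythroid, skeletal muscle and mesothelial lists had 0 of 48 members called by edgeR, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. Median, mean and test differed in sign for the glucose, oxidative phosphorylation, atrial and skeletal muscle lists.

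CEK was compared with E4BP4 FLOX for the effect of losing E4bp4 in heart muscle cells. E4BP4 FLOX carries no Cre, so the comparison also holds the effect of Cre. Beside Nfil3, Ndnf rose from 5.96 ± 1.67 to 15.7 ± 1.76 CPM (log2 fold change 1.39, SE 0.21, n = 6 per group, edgeR adjusted p = 0.000224). Its log2 fold change in Cre CON was 1.38. Nampt rose from 185 ± 13.1 to 270.0 ± 23.5 CPM (log2 fold change 0.55, SE 0.11, edgeR adjusted p = 0.00643), where CBK had a fall. Ces1d rose from 187 ± 11.5 to 312 ± 9.75 CPM (log2 fold change 0.74, SE 0.17, edgeR adjusted p = 0.0411), again where CBK had a fall. Whether the CEK and CBK changes differ was not tested directly. Nppb rose from 59.4 ± 20.7 to 131 ± 21.9 CPM (log2 fold change 1.14, SE 0.27, edgeR adjusted p = 0.0444). It also stood at 176 ± 64.3 CPM in Cre CON against 102 ± 18.6 CPM in WT (log2 fold change 0.79, not called).

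In all, 51 genes were called in CEK, 26 higher and 25 lower, 9 and 6 of them by more than 2-fold. Dcakd changed by -0.64, Ppp2r3a by -0.59, Rbfox1 by -0.60, Slc38a1 by 0.91 and Gdf15 by 1.88. Ptgds rose by 1.27, Klhdc7a by 0.88 and Irf5 by 0.88, while Tmem82 changed by -1.05 and Efnb3 by -0.60. DESeq2 called 142 genes, 61 higher and 81 lower, and a fit of these 12 libraries alone called 24, of which 18 were among the 51. Groups did not overlap for 19 of the 24 named genes called in CEK. Without 5 libraries of outlying composition 39 genes were called, 23 of them among the 51, and without a filter on low counts 17 genes were called, all among the 51. Over 11 alternatives, 1 of them with DESeq2 and the others with edgeR, adjusted p ranged from 0.00939 to 0.126 for Nppb, from 0.00395 to 0.0849 for Gdf15 and from 6.77e-06 to 0.103 for Ces1d.

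In CEK, Nfil3 was the 1 clock gene of 24 called (1 adjusted over the list alone, camera adjusted p = 2.27e-06), and the 1 called among 5 genes with REV-ERB and ROR elements (1 adjusted over the list alone, camera adjusted p = 3.77e-09). Both results contain the deletion itself: without Nfil3, camera adjusted p was 0.0223 for the other 23 clock genes and 0.543 for the other 4 genes. The 15 E-box targets had a median log2 fold change of -0.15 with 0 called by edgeR or DESeq2 and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.00142, adjusted p = 0.26 with an estimated correlation). Among 34 genes of glucose metabolism Pfkfb1 at -0.79, Pdk2 at -0.37 and Slc2a4 at -0.29 fell (adjusted over the list alone, 8 fell and 1 rose), and camera adjusted p was 0.00132 (adjusted p = 0.165 with an estimated correlation). Bckdhb at -0.36 was the 1 called of 25 genes of branched-chain amino acid and ketone catabolism (6 lower adjusted over the list alone, camera adjusted p = 1e-05, adjusted p = 0.165 with an estimated correlation). Fatty acid oxidation genes had 0 of 38 called by edgeR, 1 by DESeq2 and 12 at an unadjusted p under 0.05 (1 lower adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.165 with an estimated correlation). Macrophage markers (5 of 18 higher adjusted over the list alone, median 0.35, camera adjusted p = 1.1e-07) and inflammatory cytokines (4 of 24 higher adjusted over the list alone, camera adjusted p = 0.0003) shifted up with 0 called over all genes. Cre CON alone had medians of 0.34 and 0.29 for these lists, and neither list passed against the Cre effect (camera adjusted p = 0.995 and 0.724). For these 2 lists DESeq2 called 2 and 1 genes, and 8 and 10 had an unadjusted p under 0.05. Interferon genes shifted up (0 of 25 called, 1 higher adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.474 with an estimated correlation), and over 6 alternatives the adjusted p ranged from 0.000146 to 0.842, the latter without the 5 libraries. Nppb, Gdf15 and Nampt were the 1 member called in the hypertrophy, stress response and antioxidant lists. In all, 24 lists of 504 memberships had 0 called, with 92 at an unadjusted p under 0.05 and 8 by DESeq2. Median, mean and test differed in sign for the triglyceride, insulin, antioxidant, endothelial and lymphocyte lists, which did not pass.

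The atrial gene Bmp10 stood at 57.7 ± 43.2 CPM in CEK and 0.649 ± 0.818 CPM in E4BP4 FLOX, a difference that was not called (edgeR adjusted p = 0.207). Bmp10 was chosen after its values were seen. Atrial markers as a list did not pass in CEK (camera adjusted p = 0.0676).

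CBK/CEK was compared with BMAL1/E4BP4 FLOX for the effect of losing both genes, which here also holds that of Cre. Dbp fell from 105 ± 17.9 to 32.5 ± 4.65 CPM (log2 fold change -1.69, SE 0.18, n = 6 per group, edgeR adjusted p = 9.72e-10) and Nr1d2 from 92.7 ± 9.01 to 33.8 ± 3.33 CPM (edgeR adjusted p = 2.37e-15). Cdkn1a rose from 10.5 ± 3.62 to 114 ± 19.6 CPM (log2 fold change 3.42, SE 0.25, edgeR adjusted p = 5.86e-14), and Slc41a3 from 31.0 ± 6.54 to 235 ± 16.5 CPM. Tcap fell from 2567 ± 744 to 464 ± 102 CPM (log2 fold change -2.47, SE 0.23, edgeR adjusted p = 7.58e-11). Nampt fell from 186 ± 29.4 to 129 ± 18.5 CPM (SE 0.11, edgeR adjusted p = 0.00045). Ces1d fell from 178 ± 29.6 to 95.5 ± 13.2 CPM (log2 fold change -0.90, SE 0.17, edgeR adjusted p = 0.000295).

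In all, 975 genes were called in CBK/CEK, 493 higher and 482 lower, 123 and 128 of them by more than 2-fold. A fit of these 12 libraries alone called 705, and in simulated data 11.5% of the calls of the pooled fit were false for this line. Iyd rose by 5.81, Cbln1 by 3.80, Sprr1a by 3.74, Mrln by 3.37 and Fut2 by 2.81. Pde11a changed by -3.93, Myot by -2.42 and Bdh1 by -2.03. Ighg2c fell from 5.95 ± 1.61 to 0.428 ± 0.240 CPM. Groups did not overlap for 66 of the 83 named genes called in CBK/CEK.

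Clock genes moved in CBK/CEK mostly as in CBK. Of 24, 5 rose and 11 fell (5 and 13 adjusted over the list alone, camera adjusted p = 3.82e-05), with Npas2 at 2.17, Cry1 at 1.35, Clock at 1.16, Ciart at -1.96, Per3 at -1.02 and Hlf at -0.91. Of 15 E-box targets, 9 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 7.1e-20). Of the 5 genes with REV-ERB and ROR elements, 4 rose and Nfil3 fell (4 and 1 adjusted over the list alone, camera adjusted p = 1.79e-09). Arntl, also targeted in this line, is among those that rose, and the list was not tested without it. Of 20 hypertrophy and fetal genes, 4 rose (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00382, adjusted p = 0.121 with an estimated correlation), with Rcan1 at 1.78 and Nppb up from 79.0 ± 23.7 to 191 ± 51.6 CPM. Of 41 ion channel genes, 6 rose and 4 fell (9 and 8 adjusted over the list alone), with Hcn2 at 1.60, Gja1 at 0.46, Casq2 at 0.46 and Hcn4 at -1.24. Kcnip2 fell from 180.0 ± 23.5 to 136 ± 8.46 CPM (log2 fold change -0.41). Of 20 sarcomere genes, 4 rose, Mybpc3 by 0.47, and Tcap fell (4 and 2 adjusted over the list alone). Atrial markers shifted up with 0 of 10 called by edgeR or DESeq2 and 2 at an unadjusted p under 0.05 (median 0.63, camera adjusted p = 0.0284, adjusted p = 0.855 with an estimated correlation).

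Of the metabolic lists in CBK/CEK, camera passed branched-chain amino acid and ketone catabolism (6 of 25 lower over all genes, 6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00193, adjusted p = 0.324 with an estimated correlation), with Bckdhb at -0.57 and Dbt at -0.49. Of 38 fatty acid oxidation genes, 7 fell, with Ech1 at -0.59 and Hadh at -0.39, and Pdk4 rose by 1.46 (8 and 1 adjusted over the list alone). Of 26 lipid synthesis genes, 2 rose, Scd4 by 1.85 and Agpat3 by 0.74, and 3 fell, with Dgat2 down from 407 ± 30.4 to 143 ± 41.9 CPM (4 and 4 adjusted over the list alone). Counts of Scd4 may miss reads shared with near-identical copies. Of 34 glucose metabolism genes, 4 rose and 4 fell (6 and 6 adjusted over the list alone), with Hk2 at -0.63 and Slc2a4 at -0.38. Of 28 insulin signalling genes, Ddit4 rose by 1.32 and 3 fell, with Pik3ip1 at -0.56 (1 and 7 adjusted over the list alone). The other lists had 0 to 3 called members each, such as Herpud1 at -0.61, Nqo1 at 0.49, Lamp1 at 0.44, Ccn2 at 1.29, Ccr2 at 1.41, Abcc9 at -0.70, Ier3 at -0.96 and Cenpf at -1.27. In CBK/CEK, 10 lists of 151 memberships had 0 called by edgeR, with 12 at an unadjusted p under 0.05 and 1 by DESeq2. Median, mean and test differed in sign for the ion channel, stress response, immediate early and mural lists, which did not pass.

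The change in CBK/CEK was set against the change in CBK to ask whether the loss of E4bp4 altered what the loss of Bmal1 does. Ces1d fell less in CBK/CEK, by a difference of 3.29 in log2 fold change (SE 0.25, edgeR adjusted p = 9.68e-13). Rhobtb1 differed by 1.70 (SE 0.17, edgeR adjusted p = 4.23e-10), with 30.5 ± 5.60 CPM in CBK against 139 ± 27.8 CPM in BMAL1 FLOX, and 103 ± 17.7 CPM in CBK/CEK against 144 ± 13.0 CPM in BMAL1/E4BP4 FLOX. The cell-cycle kinase gene Wee1 differed by 1.73 (edgeR adjusted p = 1.49e-07), Kcnip2 by 0.79 (edgeR adjusted p = 0.000312) and Oplah by 1.06. Nampt, at 129 CPM in CBK/CEK and 41.0 CPM in CBK, also differed (edgeR adjusted p = 1.85e-09). In all, 27 genes differed, 24 with a higher fold change in CBK/CEK and 3 with a lower one, among them Nfil3 at -4.18 (edgeR adjusted p = 4.75e-20) and P4ha2 at -0.52. Without WT replicate 1, P4ha2 was no longer called (edgeR adjusted p = 0.0554), and over 10 alternatives its adjusted p ranged from 0.00895 to 0.163. Camera passed 6 of the 31 lists for this difference and 1 with an estimated correlation, the genes with REV-ERB and ROR elements, whose median was 0.21, mean -0.64 and test down. Without Nfil3 that list did not pass (camera adjusted p = 0.201).

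The effects of the single knockouts were added, with the effect of Cre counted once, and compared with the effect of losing both genes. Ces1d departed from that sum by 2.41 (SE 0.35, n = 6 per group, edgeR adjusted p = 0.000149) and Rhobtb1 by 1.57 (SE 0.23, edgeR adjusted p = 0.000149), both upward. Rhobtb1 stood at 153 ± 9.04 CPM in CEK and 149 ± 11.4 CPM in E4BP4 FLOX. Ces1d and Rhobtb1 were the 2 genes called by edgeR, with 980 at an unadjusted p under 0.05 (831 expected by chance), and DESeq2 called 7.

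**Figure D3:**
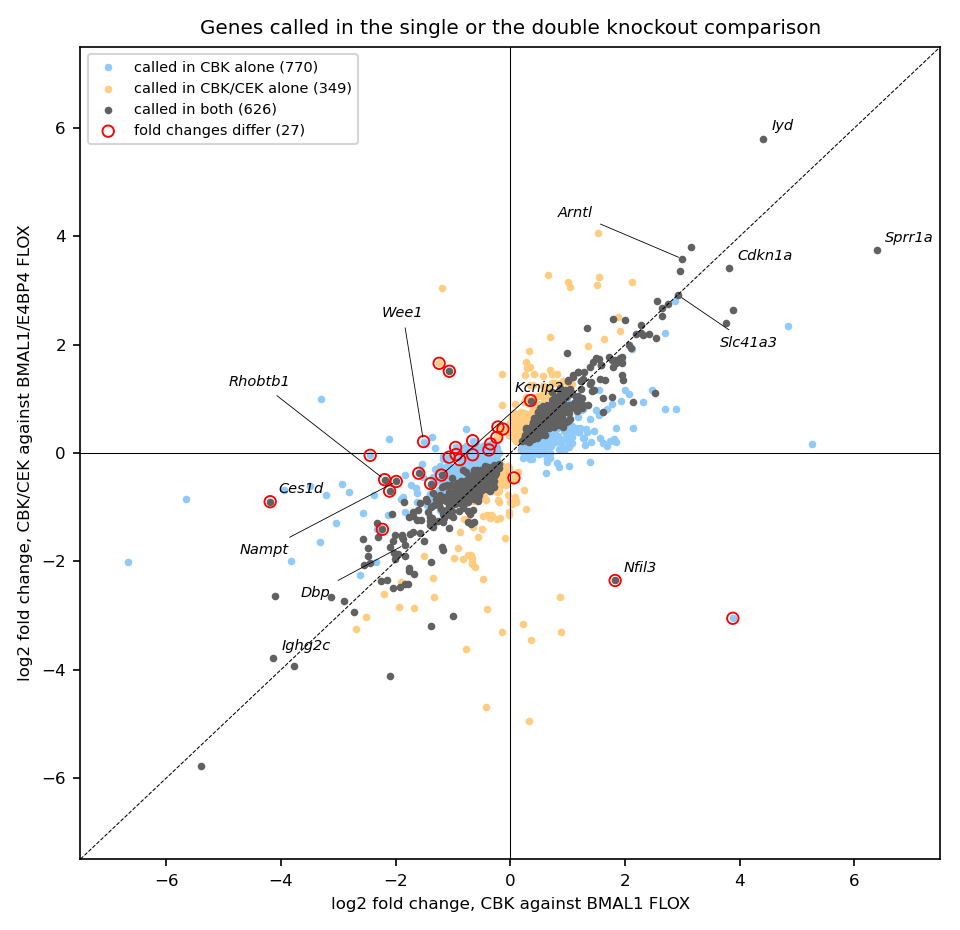
Log2 fold change in CBK (horizontal) against that in CBK/CEK (vertical), a point per gene called in either, from 6 against 6 libraries each. In all, 626 genes were called in both, 770 in CBK alone and 349 in CBK/CEK alone; red rings mark the 27 genes whose fold changes differed.

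Each knockout's change was also compared with that of Cre alone. Ces1d differed from the Cre effect by -4.04 in CBK (edgeR adjusted p = 8.95e-16, n = 6 per group), Mid1ip1 by -1.95, Slc41a3 by 2.76, Nfil3 by 1.88, Ypel2 by 1.75 and Hcn2 by 1.47, among 411 genes called, 208 higher and 203 lower. In CBK/CEK, Slc41a3 differed by 2.75 (edgeR adjusted p = 6.47e-14), Ypel2 by 1.64, Gstm7 by 1.15, Nr1d2 by -1.33, Emilin2 by -1.60 and Ighg2c by -3.35, among 223 genes called, 127 higher and 96 lower. In CEK, Nfil3 alone was called by edgeR (SE 0.25, edgeR adjusted p = 6.23e-15), while 648 genes had an unadjusted p under 0.05 (831 expected by chance) and DESeq2 called 5. Without Cre CON replicate 1, 2 genes were called in CEK. These contrasts share the Cre CON and WT libraries. Camera passed 8 lists for CBK, 5 for CEK and 8 for CBK/CEK, of which 3, 1 and 2 passed with an estimated correlation. E-box targets stayed lower in CBK (10 of 15 lower over all genes, 12 adjusted over the list alone, camera adjusted p = 2.08e-23) and in CBK/CEK (5 over all genes, 9 adjusted over the list alone, camera adjusted p = 3.27e-14). Hypertrophy genes stayed higher in CBK (3 of 20 over all genes, 6 adjusted over the list alone, camera adjusted p = 7.94e-06) and did not pass in CBK/CEK (0.0503). Other lists that passed in CBK against its controls did not pass against the Cre effect: branched-chain amino acid and ketone catabolism (camera adjusted p = 0.236), fatty acid oxidation (0.882), extracellular matrix (0.259), the p53 response (0.282) and clock genes (0.176, and 0.0095 without Nfil3, which rose in CBK). In CBK/CEK the same held for branched-chain amino acid and ketone catabolism (camera adjusted p = 0.685). In CEK it held for E-box targets (camera adjusted p = 0.553), fatty acid oxidation (0.724), branched-chain amino acid and ketone catabolism (0.724), glucose metabolism (0.33) and interferon genes (0.119).

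CBK and CBK/CEK shared 626 called genes, while 770 were called in CBK alone and 349 in CBK/CEK alone. Of the shared genes, 301 rose in both against 19.96 expected of independent sets, and 323 fell in both against 20.96 expected. Nfil3 and the unnamed gene model Gm33424, chosen after its values were seen, moved in opposite directions. Of the 1396 genes called in CBK, 1335 (95.6%) had the same sign in CBK/CEK, and the log2 fold changes of those genes correlated at a Pearson r of 0.834 across genes, which are not independent replicates. Over all genes r was 0.352 and Spearman's rho 0.329. CEK and CBK shared 9 genes called higher and 13 called lower, against 1.05 and 1.09 expected. Nampt, Ces1d, Ptgds and Gm33424 were called lower in CBK and higher in CEK. CEK and CBK/CEK shared 10 higher and 14 lower, against 0.77 and 0.72 expected. Ndnf, Dcakd and Ppp2r3a were called in the same direction in all 4 lines, and 19 genes were called alike in the 3 knockouts, including Nppb, Pfkfb1, Slc2a4 and Bckdhb. Of the 51 genes called in CEK, 46 (90.2%) had the same sign in Cre CON.

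**Figure D4:**
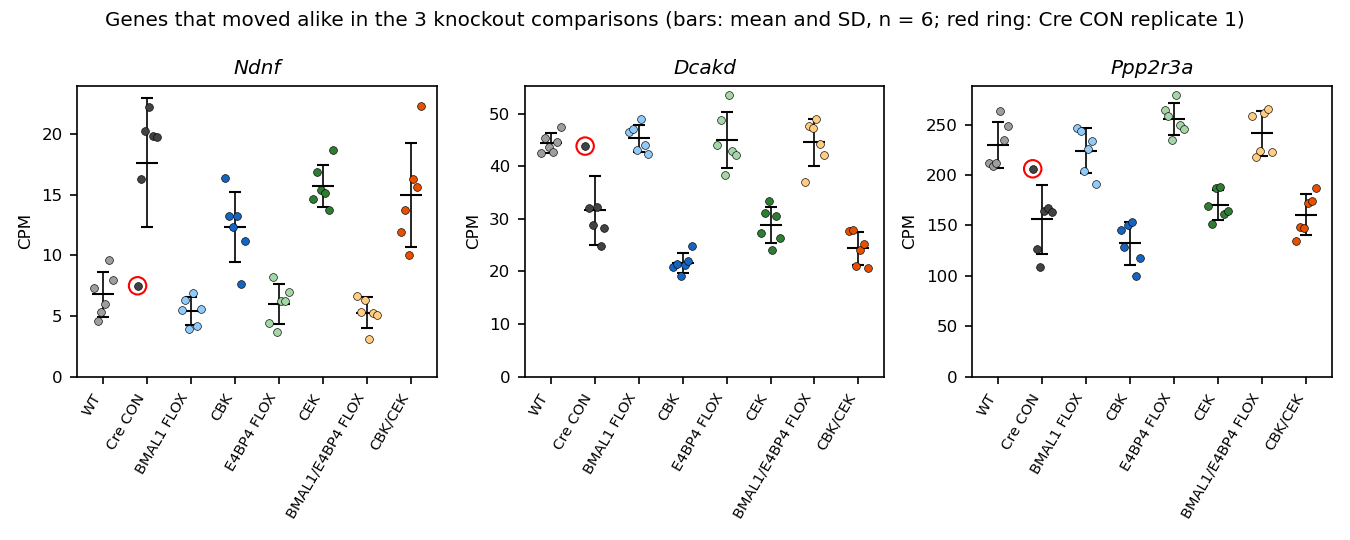
Normalised CPM (linear axes) of Ndnf, Dcakd and Ppp2r3a per library in the 8 groups, bars the mean and SD of 6; a red ring marks Cre CON replicate 1. Ndnf stood at 17.6 CPM in Cre CON and 6.78 CPM in WT.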

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

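Tests chosen only after the result was seen were those of a mislabelled or swapped Cre CON replicate 1, of the floxed controls against WT and of the chromosomes of the floxed genes, and of the CEK genes in Cre CON; the splits of the libraries and the depth test were planned.

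Some libraries stood apart from the other 5 of their group, by Dixon's test at the 95% level. BMAL1/E4BP4 FLOX replicate 6 held 13.13 M assigned counts against 21.41 M in the nearest, and ENSMUSG00000119584 took 34.77% of its counts against 2.87%. WT replicate 1 held 126.34 M against 18.3 M, with 23787 genes detected against 20703. E4BP4 FLOX replicate 3 had 17931 genes detected against 19353, and CBK replicate 3 had 13.35% of its counts on ENSMUSG00000119584 against 2.21%. In single genes, Arntl stood at 1.713 CPM in E4BP4 FLOX replicate 4 (nearest 0.927), and CBK replicate 5 stood at 18.138 CPM for Ces1d (nearest 8.371) and 1391.982 CPM for Tcap (nearest 780.994). Chance picks out about 1 in 20 groups. Of 32 groups of library measures 6 stood out against 1.6 by chance, and of 86 groups of gene levels 3 stood out against 4.3 by chance.

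Effects that differed between lines under a test of the difference were counted. Against Cre alone, 411 genes differed in CBK, with Ces1d and Slc41a3 among them, 223 in CBK/CEK and 1 in CEK, Nfil3. Between CBK/CEK and CBK, 27 genes differed, and 2 genes, Ces1d and Rhobtb1, departed from the sum of the single knockouts.

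Chance as a source of the counts was tested by splitting the 12 libraries of every line into other groups of 6, 100 splits with the real one included. For CBK, the real 1396 genes were reached by 1 split, the real one, with 919 the highest of the others. For CEK 1 split reached 51 (highest other 2), for CBK/CEK 1 reached 975 (139), and for Cre CON 1 reached 3 (1). For the differences from Cre, 1 split reached 411 in CBK (9), 3 reached the 1 gene in CEK (1), and 1 reached 223 in CBK/CEK (2). For CBK/CEK against CBK, 4 splits reached 27, with 448 the highest other, and for the departure from the sum 2 reached 2, with 20 the highest other. Each share was under 0.05, without adjustment over the contrasts, and chance is argued against for the lines and the differences from Cre. For CBK/CEK against CBK and the departure from the sum, other splits gave more calls than the real one. Chance therefore stays open for those counts. Other splits also mix knockout and control libraries within a group, which widens the spread, so their low counts are partly built in. The split with 919 genes had 4 of 6 CBK-line libraries on their true side, which is common among such splits. In splits with CBK replicates 3 and 5 on the same side, 7 of 40 gave any call in CBK (highest 919), and 4 of 59 did where they were parted (highest 501). The cause of the counts of 919, 448 and 20 was not tested.

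Cre CON replicate 1 sat near WT level for genes that went with Cre. Over 19 genes called alike in the 3 knockouts, its mean signed log2 difference from WT was 0.127, while the highest WT library stood at 0.12 and the other 5 Cre CON libraries at 0.524 to 0.876. Ndnf stood at 7.48 CPM in it, 6.78 CPM in WT and 19.66 CPM in the other 5. A swap with a WT library is argued against, since the highest WT score, 0.12, lies far below 0.524, and so is low depth, since the other 5 thinned to its depth still scored at least 0.514. A wrong label stays open, since 0.127 lies neither at or below the WT range nor above it by more than the WT spread of 0.063, and no biological explanation was tested.

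BMAL1 FLOX, which carries no Cre, differed from WT in 44 genes. Of the 43 with a known position, 24 (55.8%, exact 95% interval 39.9 to 70.9) lie on the chromosome of Bmal1, against 7.8% of tested genes (Fisher's exact p = 3.34e-16). Of the 19 elsewhere, 6 are processed copies of Rps13 and Rps15a. A batch as the whole cause is argued against, since the interval starts at 39.9% and a batch has no reason to favour that chromosome, and the excess is consistent with a strain variant in DNA linked to the floxed gene. In E4BP4 FLOX edgeR called 0 genes (1045 at an unadjusted p under 0.05, 831 expected by chance, DESeq2 not run for this contrast). Genes called in CBK lay on the chromosome of Bmal1 at 7.4%, no more than the 7.8% of tested genes. Among 1396 calls that share could hide an effect on as few as 24 genes. Of the 44 genes, 5 were also called in CBK, so a mark on the comparison with littermates stays open. On the chromosome of Nfil3, with Nfil3 itself left out, lay 4 of 50 CEK calls (Fisher's exact p = 0.127) and 50 of 971 CBK/CEK calls (5.1%, Fisher's exact p = 0.0236), against 3.9% of tested genes, and the source of the latter was not tested.

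Of the 50 genes other than Nfil3 called in CEK, 45 had the same sign in Cre CON, whose libraries did not choose them. Their median change in the CEK direction was 0.32 in Cre CON, against a median size of 0.66 in CEK, and a rotation (permutation-type) test gave p = 5e-06, the smallest its rotations can give. The unnamed abundant gene ENSMUSG00000119584 as the whole cause is argued against, since 38 of the 50 were still called with its level as a covariate. A candidate explanation for part of the CEK calls is Cre recombinase itself, given the shared signs and the rotation test. CEK minus Cre left Nfil3 alone called by edgeR, but a lack of calls there does not show that a gene follows Cre. Nampt and Ces1d, at 0.55 and 0.74 in CEK against -0.14 and -0.15 in Cre CON, were not called there either. A contribution of E4bp4 on top stays open. The smaller Cre change of the median gene cannot decide it, since the genes were chosen by their change in CEK. Cre CON replicate 1, near WT level, also lowers the Cre value, which was 0.355 without it. Removing the library nearest to WT raises that value in part by construction. EdgeR called none of the 50 differences from the Cre effect. DESeq2 called 5 genes, Nfil3 included, and edgeR called 2 without Cre CON replicate 1.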

How the results depend on the processing

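The fits without single or outlying libraries and with ENSMUSG00000119584 as a covariate, the lists without Nfil3, and the count of shared genes in the lines alone, were chosen after the data were seen; the other tests were planned. No named gene, and no list that passed in the 4 lines, changed sign under an alternative. For CBK/CEK minus CBK, the list of genes with REV-ERB and ROR elements turned from down to up without Nfil3 (camera adjusted p = 0.201). The balance of directions in CBK (673 higher and 723 lower) turned with RLE (751 and 660), DESeq2 (880 and 755), a filter of 1 CPM (812 and 673), its line alone (440 and 417) and without the 5 libraries (798 and 662), and in CEK (26 and 25) under 5 alternatives, such as DESeq2 (61 and 81). It also turned in CBK/CEK (493 and 482) under 3, such as no filter (373 and 385), in Cre CON (1 and 2) with DESeq2 (11 and 8) and in its line alone (9 and 3), and in CBK minus Cre (208 and 203) with no filter (151 and 159).

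The count for CBK against BMAL1 FLOX was 857 (825 shared with the 1396) in a fit of that line's 12 libraries alone, whose wider spread the pooled model lowers. CEK gave 142 with DESeq2, 17 without a filter and 24 (18 shared with the 51) in its line alone. Cre CON gave 19 with DESeq2, which set no adjusted p for 4514 genes, 12 (0 shared with the 3) in its line alone, 16 without Cre CON replicate 1 (3 shared), 6 without the 5 outlying libraries and 4 without WT replicate 1. CEK minus Cre gave 5 with DESeq2, 2 without Cre CON replicate 1 and 1 without WT replicate 1. The departure from the sum gave 7 with DESeq2. Lists passing in the 4 lines numbered 37 with the preset correlation, 17 with an estimated one and 28 with fry. Without a filter, 34803 genes were tested; for the other changes the cause was not tested.

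With a replicate block the 9 counts were 1385, 42, 942, 3, 401, 1, 227, 28 and 2, in the order CBK, CEK, CBK/CEK, Cre CON, the 3 differences from Cre, CBK/CEK minus CBK, and departure from the sum. Residuals of libraries with the same number correlated at -0.169 to 0.253, and a library was closest to its own number in 1, 1, 3 and 2 of 6 cases. The mean correlation was 0.086 in CBK, -0.041 in CEK, 0.053 in CBK/CEK and 0.045 in Cre CON. For libraries of other numbers it was -0.016, 0.009, -0.009 and -0.009. These small values do not settle whether the numbers mark pairs. With the cohort covariate the counts were 1426, 51, 1029, 3, 412, 1, 232, 28 and 3. The 624 genes shared by CBK and CBK/CEK became 420 at an adjusted p of 0.01, 706 with DESeq2, 423 in the lines alone and 707 without the 5 libraries.

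Of 185 pairs of a named gene and a comparison, 154 stayed called under each alternative run and 31 were lost under some, none with a changed sign. No filter lost 22, line alone 22 of 155, the 5 libraries 16, the replicate block 4, the ENSMUSG00000119584 covariate 4, the cohort covariate 3, RLE 2, WT replicate 1 2, and DESeq2, the 1 CPM filter and Cre CON replicate 1 lost 0. Lost under 3 or more were Nppb, Gdf15, Slc2a4, Bckdhb, Irf5, Pdk2 and Ptgds in CEK, Kdr, Gbp3 and Cenpf in CBK, Lcn2 and Lyve1 in CBK/CEK, and P4ha2 in CBK/CEK minus CBK. Depth limits genes near 1 CPM, such as Arntl in controls, and at 6 animals per group about 50% of simulated 1.5-fold changes were recovered (50.7% in CBK), so a gene not called may have changed that much.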

Other observations

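The tests of both hypotheses below were chosen only after the results were seen.

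Of the 1396 genes called in CBK, 1335 had the same sign in CBK/CEK and 626 were called there as well. Both lines carry Cre, and its part was not subtracted from these numbers. Ces1d, Nampt, Kcnip2, Rhobtb1 and F3 fell less in CBK/CEK, and Wee1 did not fall (0.21). F3, which encodes tissue factor, differed between CBK/CEK and CBK by 1.23 in log2 fold change. Of the 24 genes with a higher fold change in CBK/CEK, 19 were called lower in CBK. Their median log2 fold change was -1.07 in CBK, -0.03 in CBK/CEK and 0.09 in CEK. The first 2 values share libraries with the choice of the genes, so the return toward 0 is partly built in.

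A hypothesis is that E4BP4, whose transcript rose in CBK, may repress these genes, and does so also where Bmal1 is intact. The CEK line, whose libraries did not choose them, gave the test. There 19 of the 24 had a positive sign and 4 were called higher: Nampt, Ces1d, the gene model Gm33424 and Cp. Cp, chosen after its values were seen, was also called higher in CBK, at 0.35, where the hypothesis predicts a fall. It stood at 0.39 in CEK and 0.22 in Cre CON. The rotation p for a rise of the 24 genes was 2e-05 (1e-05 without the 5 outlying libraries). In Cre CON the same test gave 0.915. The median of 0.09 in CEK is small, and the largest rises were those of Gm33424 at 1.74, Ces1d at 0.74 and Nampt at 0.55. Rhobtb1 at 0.04, Kcnip2 at 0.02 and Coq10b at 0.01 barely changed in CEK, and Mid1ip1 was at -0.11. The test thus speaks for the set and not for each gene.

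A second hypothesis was that repression by E4BP4 could be the general route by which genes fall in CBK. The 723 genes called lower in CBK had a median of -0.60 there and -0.381 in CBK/CEK, where 681 of them were lower and 19 differed between the lines. The median fall in CBK/CEK was thus more than 0.5 of that in CBK, where the hypothesis predicted less. Both lines carry Cre, however, and 70.2% of the 1396 genes called in CBK had the same sign in Cre CON. That part was not subtracted, so the test cannot decide the route for most of the 723 genes.

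Alb and Apoa1, genes of the liver, stood out in single libraries. Alb reached 385 CPM in WT replicate 1, 169 CPM in CBK replicate 5 and 136 CPM in BMAL1 FLOX replicate 5, and Apoa1 stood at 70.7, 62.2 and 17.7 CPM in the same libraries. Bmp10 ranged from 0.09 to 126.8 CPM within CEK. These genes were chosen after their values were seen. The first principal component held 12.5% of the variance and the second 9.4%.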
